A study of Bos taurus with 12 samples.

How the data were processed

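RNA from jugular blood of 12 Holstein cows, drawn on day 7 after calving, was sequenced on an Illumina NovaSeq instrument after haemoglobin depletion, per the labels' protocols; the labels name the material both as blood and as white blood cells. The submitters' processing notes name FastQC, STAR, featureCounts and DESeq2 and the genome build ARS-UCD1.2, without versions or roles. The annotation and the strand setting of the counting are not given in the sources used here, so reads from overlapping, antisense or near-identical genes cannot be told apart in these counts. The gene counts were used as deposited, as raw whole numbers for each gene and library. The authors also deposited a filtered count table, which holds the 14288 genes whose mean of the 2 group sums is at least 10. Their DESeq2 table gives a mean normalised count (a signal over all libraries), a log2 fold change with its standard error, a Wald score, and p-values with adjusted p-values, per the file headers. A deposited sequencing summary gives the count of clusters and the yield of each library, the percent of bases above a quality threshold and a mean quality score, per the file headers. Glutathione peroxidase and superoxide dismutase activities, AC, TBARS, OSi and milk were deposited for each cow with neither unit, assay nor material stated in the sources used here. OSi equalled TBARS divided by AC of the same cow and day within 4.29e-10. In the SOD sheet 2 values were missing (supplemented cows 3 and 6 on day 4), and TBARS took 23 distinct values over 48 cells.

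Cows were assigned to groups by the treatment label, and replicate numbers only name the cows and pair nothing. The samples are separate animals per the labels, and no 2 libraries agreed within sampling noise (lowest chi-square per degree of freedom 12.3). Groups, tests, gene lists and most alternative settings were fixed before the data were examined. Genes with a mean raw count of at least 10 over the 12 libraries were tested, 11990 of 27429. The main test was edgeR's quasi-likelihood test with TMM scaling and robust dispersion, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.476. Standard errors of edgeR fold changes were taken as the fold change divided by the square root of the F statistic. CPM values are TMM-normalised, and log2 CPM used a prior count of 2. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

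The 22 pathway lists and 12 cell type marker lists held 821 gene names, of which 745 were found by symbol in the count table, 4 through a synonym (among them GSTM1 as GSTM4 and CATHL7 as CAMP) and 72 were not found. A list was tested with at least 5 genes past the count minimum, which left 33 lists; basophil and mast cell markers (4 genes) were compared as a score only. Lists were tested with limma's camera with an estimated inter-gene correlation, two-sided, which compares a list with the other genes. Some genes stand in several lists, such as SOD2 in the antioxidant and the NF-kB list. All immature granulocyte markers that were tested also stand in the neutrophil granule list. Named genes followed a rule fixed beforehand: the genes with the largest changes among those past the threshold or, with fewer than 3 in a direction, the 5 with the lowest p in it with a gene name and at least 5 CPM; up to 4 members of each list that passed; 20 fixed genes; and the most counted gene of each library. Where other genes are named, the text says that they were chosen after their values were seen.

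Marker scores, library measures, biochemical determinations and milk were compared by exact two-sided permutation over the 924 splits of 6 against 6 cows, with Benjamini-Hochberg adjustment within each family. Correlations used 100000 permutations. The edgeR step was tested on simulated data with 200 of 11990 genes changed in the comparison of supplemented with control cows. In negative binomial draws it recovered 0% of genes changed 1.5-fold, 15.5% of those changed 2-fold, 81.5% at 4-fold and 92.5% at 8-fold, and in thinned real libraries 0%, 27%, 73.5% and 87%. Differences of 2-fold or less in single genes were therefore mostly below what these 6 against 6 libraries can show. At an unadjusted p under 0.05, the list test called a 30-gene list raised 1.5-fold as higher in 10 of 10 draws and an unchanged list in 0 of 10. Calls as lower were not counted and no adjustment over lists was made, so these are not the rates of the main list test. The draws held no correlation between genes, whereas estimated correlations in the real lists reached 0.864, so this recovery does not carry over to correlated lists. Alternatives were DESeq2, limma-voom with and without sample weights, other scalings, other filters, omission of haemoglobin genes, a minimum fold change, covariates for cell type markers, for base quality and for a surrogate variable, a preset correlation and fry for lists, other summaries and scales for the determinations, and omission of each library or cow. The authors' filter with edgeR and with DESeq2, the B cell minus T cell score and the first index as covariates, and omission of both libraries with the highest neutrophil scores were added after the data were seen. DESeq2 run here on the authors' filtered genes gave fold changes with a correlation of 1 over genes to the authors' deposited table.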

Results

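Gene expression in peripheral blood was compared between Holstein dairy cows that had received an injected trace element supplement around calving and control cows. Blood was drawn from the jugular vein on day 7 after calving, and RNA was sequenced from 6 supplemented and 6 control cows, with 1 library for each cow. Which elements were given, at what dose and on which day, is not given in the sources used here. The count table held 27429 genes, and the total count ranged from 6.78 M in supplemented cow 2 to 16.9 M in supplemented cow 6. Supplemented libraries held 11.2 ± 4.32 M counts (SD, n = 6) and control libraries 8.34 ± 1.76 M (SD, n = 6; exact two-sided permutation p = 0.167). The same cows had 5 biochemical determinations on days 0, 4, 7 and 14, and a milk value on day 30.

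The first comparison asked which transcripts differed between supplemented and control cows on day 7. No transcript was separated from the spread between cows: 0 of the 11990 genes tested had an adjusted p under 0.05 in edgeR's quasi-likelihood test, and the lowest adjusted p was 0.999. At an unadjusted p under 0.05 there were 191 genes, 112 with a higher and 79 with a lower level in supplemented cows, where 600 would be expected by chance alone. DESeq2 on the same genes gave 2 genes and limma-voom gave 0. Genes with the lowest p values among named genes of at least 5 CPM are therefore given as values that did not pass. On the higher side were NSF, an ATPase of vesicle fusion (log2 fold change 0.59 ± 0.17, SE), and MAD2L1, a spindle checkpoint protein (1.21 ± 0.35), followed by ARFIP1 (0.42 ± 0.13) and the ETS transcription factor ELF1 (0.39 ± 0.12). On the lower side were SCRN3 (-0.99 ± 0.26), a signal recognition particle RNA named Metazoa_SRP (-0.95 ± 0.25), UROS, an enzyme of haem synthesis (-0.83 ± 0.23), OR2I1P (-1.06 ± 0.30) and MAPK8IP2 (-0.98 ± 0.28). Each of these genes had an edgeR adjusted p of 0.999. NSF averaged 53.2 ± 11.2 CPM in supplemented and 35.3 ± 6.36 CPM in control cows (SD, n = 6 each), and SCRN3 averaged 3.35 ± 0.983 against 6.72 ± 1.75 CPM.

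Fixed genes of selenium, copper, zinc and manganese biology are given as values, since none of them passed. GPX1, the cytosolic glutathione peroxidase, stood at 773 ± 410 CPM in supplemented and 656 ± 159 CPM in control cows (SD, n = 6 each; log2 fold change 0.24 ± 0.29, SE). GPX4, the lipid hydroperoxide reductase, differed by 0.02 ± 0.14 and gave -0.01 with upper-quartile scaling and -0.04 with no scaling factor. TXNRD1, thioredoxin reductase, differed by 0.13 ± 0.16, SELENOP, the selenium transport protein, by -0.13 ± 0.41, SOD1, the copper and zinc superoxide dismutase, by 0.04 ± 0.18, and catalase (CAT) by 0.13 ± 0.17. MT2A, a metallothionein, averaged 5.60 ± 2.0 CPM in supplemented and 3.97 ± 0.871 CPM in control cows (log2 fold change 0.50 ± 0.26), the zinc exporter SLC30A1 differed by -0.13 ± 0.22, and the zinc and manganese importer SLC39A8 by 1.48 ± 1.02. NFE2L2, the transcription factor of the antioxidant response, differed by 0.32 ± 0.35 and HMOX1, which degrades haem, by 0.70 ± 0.61. SELENOW, MT1A and CP lay below the count minimum, at means of at most 0.201 CPM in either group. Of the 20 genes fixed beforehand, 17 were tested, and 0 passed in edgeR when adjusted over the list alone (lowest adjusted p = 0.447; 0 over all genes, and 0 with an unadjusted p under 0.05).

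The large fold changes among the fixed genes came from supplemented cow 6. SOD2, the mitochondrial manganese superoxide dismutase, reached 4926 CPM in that cow against 35.7 to 277 CPM in the other supplemented cows, so that its log2 fold change of 2.60 ± 1.24 became -0.36 without supplemented cow 6. GPX3, the plasma glutathione peroxidase, reached 68.8 CPM against at most 4.73 CPM in the other supplemented cows, and its log2 fold change of 2.08 ± 1.19 became -0.49 without this cow. GPX1 turned likewise from 0.24 to -0.09. By the same measure, TNF (log2 fold change -1.72 ± 0.95) and IL1B (-1.41 ± 1.23) rested on control cow 5, with 265 and 1697 CPM, and stood at 0.56 and 0.73 without that cow. SELENOP turned from -0.13 to 0.32 without control cow 5. Without supplemented cow 6, SLC39A8 stood at 0.44, HMOX1 at 0.07, NFE2L2 at 0.02 and TXNRD1 at 0.0027.

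**Figure D1:**
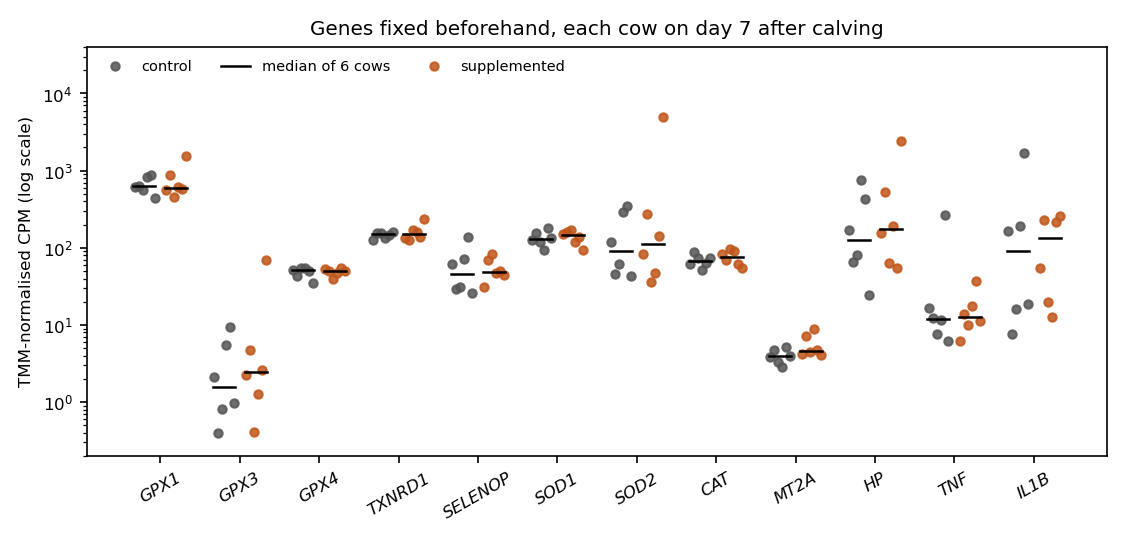
TMM-normalised CPM on a log axis of 12 fixed genes in each cow on day 7, control in grey and supplemented in orange, with the median of each group of 6 as a bar. Supplemented cow 6 holds the highest SOD2 (4926 CPM), GPX3 (68.8 CPM) and HP (2419 CPM), and control cow 5 the highest TNF (265 CPM) and IL1B (1697 CPM).

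Groups of genes were compared with 33 lists fixed beforehand. With an inter-gene correlation estimated for each list, 0 lists passed in limma's camera test (1 at an unadjusted p under 0.05), 0 passed in fry, and 8 passed with a preset correlation of 0.01. In none of the 33 lists did a member pass in edgeR, over all genes or adjusted over the list alone. No trace element list passed: of the 15 selenoprotein genes tested, 11 had a positive and 4 a negative log2 fold change (median 0.13, camera adjusted p = 0.815), and the 16 genes of metallothioneins and zinc handling had a median of 0.03 (10 positive, 6 negative, 1 with an unadjusted p under 0.05, adjusted p = 0.815). The 15 genes of copper handling had a median of 0.07 (adjusted p = 0.958), with an unadjusted p under 0.05 for the copper chaperone CCS, named after its value was seen (-0.51 ± 0.20, SE; edgeR adjusted p = 0.999), the 16 of iron and manganese handling 0.23 (13 positive, 3 negative, LCN2 with an unadjusted p under 0.05; 0.815) and the 9 of selenium incorporation -0.00028, with a positive mean of 0.05 (0.958). Of 30 antioxidant and NRF2 target genes, 21 were positive and 9 negative (median 0.13, adjusted p = 0.815). Without supplemented cow 6 the medians were 0.0027 for selenoproteins, 0.0026 for metallothioneins and zinc handling, -0.04 for copper handling, -0.0058 for iron and manganese handling, 0.08 for selenium incorporation and 0.01 for antioxidant and NRF2 target genes.

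Neutrophil granule and antimicrobial genes were the group with the largest difference. All 26 tested members had a positive log2 fold change (median 2.37), 7 with an unadjusted p under 0.05, and the list was higher with the preset correlation (adjusted p = 0.000181) but not with an estimated one (adjusted p = 0.815 with an estimated correlation). Named after their values were seen, the cathelicidins CATHL4 (7.68 ± 2.54, SE) and CATHL2 (6.82 ± 2.40), antimicrobial peptides stored in granules, and the siderophore-binding protein LCN2 (2.61 ± 1.1) had low unadjusted p values, each with an edgeR adjusted p of 0.999. HP, the acute-phase protein haptoglobin, differed by 1.16 ± 1.03, and S100A12, a calcium-binding protein of granulocytes, by 2.34 ± 1.37. The difference was carried by supplemented cow 6, where S100A12 was the most counted gene (38950 CPM) and CATHL2 stood at 949 CPM. Without this cow 19 members of the list passed the count minimum, 14 of them negative, with a median of -0.43. The rest of the 26 passed it only through this cow, so the filter largely set their positive fold changes. CATHL4 was at 39.9 CPM in supplemented cow 6 and at most 0.143 CPM in the other cows. HP and S100A12 stood at -0.36 and -0.97 without supplemented cow 6. Under the alternatives other than omission of 1 library, the list median was 0.27 to 2.42. These include omission of both libraries with the highest neutrophil scores, added after the data were seen.

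Other lists were called with the preset correlation as well. All 8 immature granulocyte markers tested are also among the neutrophil granule genes above, so their call repeats that result. Of 26 genes of leukocyte adhesion and migration, 22 were positive (median 0.41, preset adjusted p = 0.00298), and of 29 cytokines and receptors of inflammation, 22 were positive (median 0.46, preset 0.0112); glycolysis had 16 positive of 23 (median 0.41, preset 0.0442) and immature granulocyte markers 8 of 8 (median 1.91, preset 0.0161). Lower in supplemented cows were the cytosolic ribosomal proteins, with 73 of 75 negative (median -0.09, preset 5.54e-05), B cell markers, with 14 of 15 negative (median -0.22, preset 0.00783), and genes of MHC class II presentation, with 11 of 15 negative (median -0.09, preset 0.0195). All 8 calls were lost with an estimated correlation (adjusted p = 0.815 with an estimated correlation, for each). Without supplemented cow 6 the medians were -0.09 for adhesion, -0.13 for cytokines and receptors, 0.02 for glycolysis, -0.14 for immature granulocyte markers, 0.03 for ribosomal proteins, -0.02 for B cell markers and -0.05 for MHC class II genes. The MHC class II median stayed negative without each library (-0.21 to -0.05), and the B cell median was also -0.03 without supplemented cow 2.

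The list of lipid uptake and fatty acid oxidation had the lowest camera p, with 22 of 31 genes positive (median 0.22, adjusted p = 0.708 with an estimated correlation) and 0 members with an unadjusted p under 0.05; the median was 0.07 without supplemented cow 6. TNF and NF-kB response genes had 28 of 44 negative (median -0.22, adjusted p = 0.905), which became 34 of 43 positive (median 0.29) without control cow 5. Interferon-stimulated genes had a median of 0.07 over 38 genes (adjusted p = 0.905), and -0.14 without supplemented cow 6. Medians of the remaining pathway lists were 0.25 for NADPH oxidase and myeloid oxidants (adjusted p = 0.815), 0.25 for complement and Fc receptors (0.919), -0.02 for MHC class I presentation (0.905), 0.02 for the nuclear genes of the respiratory chain (0.905), -0.12 for cell cycle (0.905), 0.12 for unfolded protein and heat shock response (0.815) and 0.48 for extracellular matrix and collagens (0.815). Without supplemented cow 6 those of NADPH oxidase, complement, the respiratory chain and extracellular matrix were -0.01, -0.26, -0.0041 and -0.02, and that of unfolded protein and heat shock response was 0.04 (0.03 without supplemented cow 2).

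**Figure D2:**
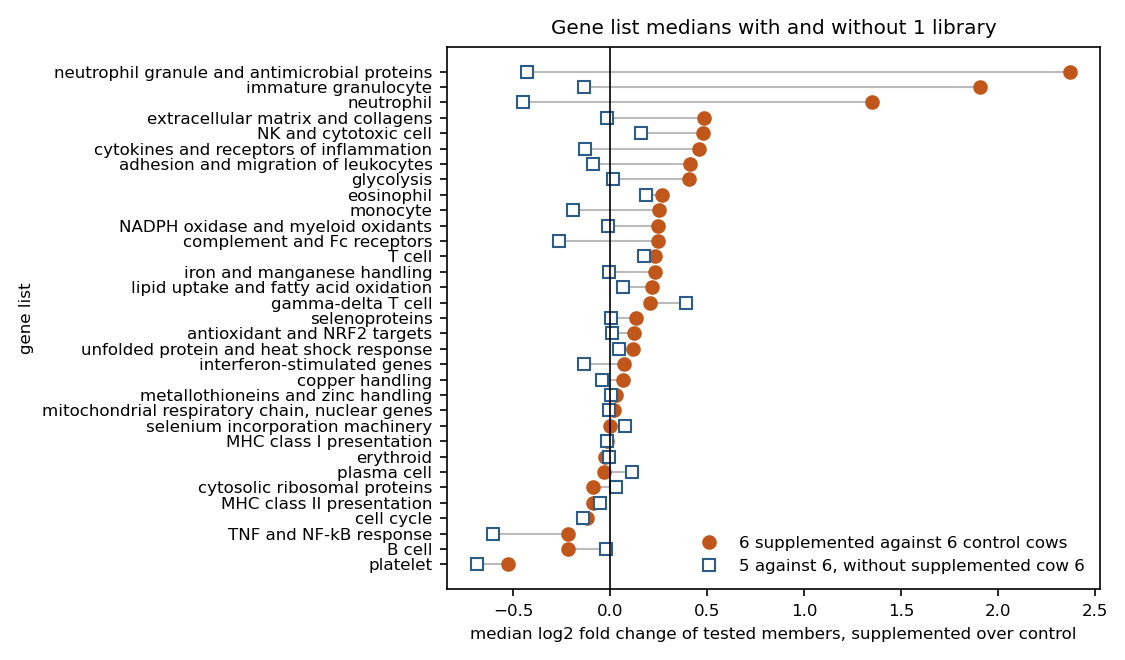
Median log2 fold change, supplemented over control, of the tested members of the 33 gene lists, with all 12 libraries (filled circles) and without supplemented cow 6 (open squares). The median of neutrophil granule and antimicrobial genes moves from 2.37 to -0.43 and that of cytokines and receptors of inflammation from 0.46 to -0.13.

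Marker genes of blood cell types were compared as a score, the mean log2 CPM over each type's markers. The neutrophil score was 5.06 ± 2.44 in supplemented and 4.26 ± 2.14 in control cows (SD, n = 6 each), a difference of 0.80, and the B cell score was 6.64 ± 1.23 against 7.07 ± 0.775, a difference of -0.44. The T cell score differed by 0.20, the monocyte score by 0.37, the NK and cytotoxic cell score by 0.22 and the immature granulocyte score by 0.94. Differences were 0.44 for eosinophils, 0.51 for basophils and mast cells, 0.05 for gamma-delta T cells, 0.03 for plasma cells, -0.17 for platelets and 0.11 for erythroid cells. The gamma-delta T cell score holds no gamma or delta receptor gene, since none was found in the count table. EPX, PRG2, PRG3, CLC and SIGLEC8 were likewise not found for the eosinophil score, so both scores are weak measures of these cells. By exact two-sided permutation tests 0 of 12 types passed (lowest unadjusted p = 0.279, adjusted p = 0.931 for each). Without supplemented cow 6 the differences were -0.11 for neutrophils, 0.08 for immature granulocytes, 0.17 for eosinophils, 0.32 for basophils and mast cells, -0.09 for B cells and 0.04 for NK and cytotoxic cells, and without control cow 6 the monocyte difference was 0.07. As lists in the camera test, neutrophil markers had 12 of 13 positive (median 1.35, adjusted p = 0.815), monocyte markers 9 of 11 (0.25, 0.815), T cell markers 16 of 18 (0.23, 0.905), NK and cytotoxic cell markers 13 of 16 (0.48, 0.905), eosinophil markers 4 of 5 (0.27, 0.815) and gamma-delta T cell markers 6 of 7 (0.20, 0.958). Plasma cell markers had 3 of 7 positive (-0.03, 0.958), platelet markers 2 of 9 (-0.52, 0.905) and erythroid markers 5 of 12 (-0.02, with a mean of 0.25, adjusted p = 0.958). Of 11 neutrophil markers 0 (median -0.45) and of 11 monocyte markers 5 (-0.19) were positive without supplemented cow 6. The rest of the 13 neutrophil markers passed the count minimum only through this cow. With 1 library left out, medians turned at the farthest to -0.04 for T cell and -0.16 for eosinophil markers without supplemented cow 2, to -0.06 for gamma-delta T cell markers without supplemented cow 4, to 0.37 for platelet markers without control cow 5, to 0.42 for erythroid markers without control cow 4 and to 0.11 for plasma cell markers without supplemented cow 6.

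**Figure D3:**
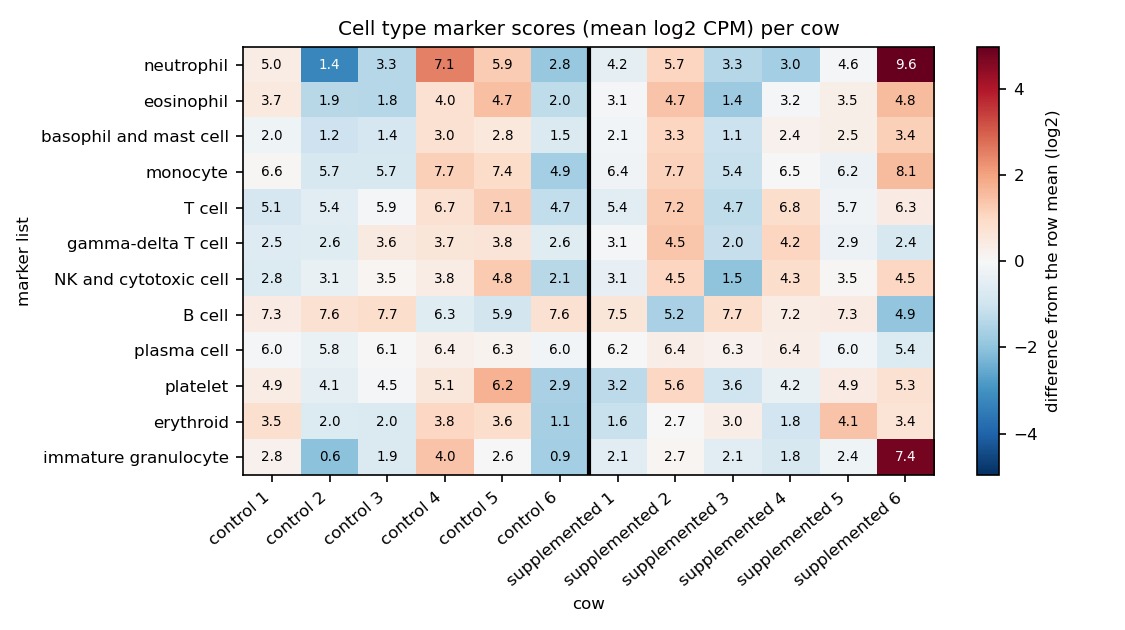
Marker score, the mean log2 CPM over each cell type's markers, for 12 cell types in each of the 12 cows, with the value in each cell and the colour giving the difference from that type's mean over cows. Supplemented cow 6 holds the highest neutrophil (9.63) and immature granulocyte (7.37) scores and the lowest B cell score (4.90).

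Only the DESeq2 fits called genes, and both calls were genes known by identifier alone, named here after their values were seen. In the authors' deposited table, ENSBTAG00000053198 had a log2 fold change of 7.21 with a standard error of 1.59 and ENSBTAG00000034185 of 3.57 with a standard error of 0.78, each with a DESeq2 adjusted p of 0.0442, among 14288 genes. In edgeR the values were 7.23 ± 1.81 and 3.57 ± 0.93 (SE), each with an adjusted p of 0.999. The deposited counts of ENSBTAG00000053198 were 6391, 3707 and 1714 in supplemented cows 4, 5 and 6 and at most 15 in every other cow. Those of ENSBTAG00000034185 were 5955, 3200 and 1157 in the same 3 cows and 55 to 131 in the other cows. The 3 cows also had the 3 deepest libraries.

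Library measures did not separate the groups: by exact two-sided permutation tests 0 of 8 measures passed after adjustment (1 at an unadjusted p under 0.05). Mean base quality was 35.79 ± 0.0216 in supplemented and 35.76 ± 0.0147 in control libraries (SD, n = 6 each; exact p = 0.039, adjusted p = 0.268). The first principal component of log2 CPM held 56.6% of the variance and the second 11.5%. EEF1A1, a translation elongation factor, was the most counted gene in 9 libraries (log2 fold change -0.14 ± 0.20) and the mitochondrial gene COX1 in 2 (0.07 ± 0.17). Haemoglobin genes took at most 0.037% of counts in any library. The first index sequence of the libraries was shared by 5 supplemented and 3 control cows, and the other by 1 supplemented and 3 control cows, so no comparison was made within the latter.

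The second comparison asked whether enzyme activities and oxidative measures differed. AC, the denominator of the deposited oxidative index, was higher in supplemented cows on day 0 (0.995 ± 0.209 against 0.648 ± 0.180) and on day 7 (0.938 ± 0.108 against 0.644 ± 0.227; SD, n = 6 each, units not stated), above the control mean in 6 of 6 supplemented cows on both days. OSi, which equals TBARS divided by AC, was 0.856 ± 0.244 against 1.31 ± 0.480 on day 0 and 0.810 ± 0.150 against 1.29 ± 0.428 on day 7, with 0 of 6 supplemented cows above the control mean. These differences did not pass the adjustment over 20 tests: by exact two-sided permutation the unadjusted p was 0.0152 and 0.0216 for AC and 0.0411 and 0.0303 for OSi, with adjusted p of 0.202, 0.202, 0.206 and 0.202. Without control cow 2, which had the highest AC (1.03) and the lowest OSi (0.531) of the control cows on day 7, AC (difference 0.371) and OSi (-0.633) on day 7 passed, each with an exact adjusted p of 0.0216. Without control cow 5 the OSi difference on day 0 was -0.273, against -0.453 with all cows. AC differed by 0.0914 on day 4 (0.0192 without supplemented cow 5) and 0.266 on day 14 (0.0987 without supplemented cow 6), and OSi by -0.060 and -0.0126.

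TBARS, a measure of lipid peroxidation products, was 0.753 ± 0.120 in supplemented and 0.768 ± 0.222 in control cows on day 7, and 0.954 ± 0.260 against 0.714 ± 0.0697 on day 14 (SD, n = 6 each; exact p = 0.0628, adjusted p = 0.251). It differed by 0.0153 on day 0 and 0.0230 on day 4. Glutathione peroxidase (GSH-Px) activity differed by 6.22, -7.27, 5.07 and 3.57 on days 0, 4, 7 and 14, against 85.4 ± 20.1 in supplemented and 80.4 ± 16.7 in control cows on day 7. The day 0 difference was 0.395 without control cow 1 and that of day 4 was -2.51 without control cow 6, while those of days 7 and 14 turned at the farthest to -2.73 without supplemented cow 4 and to -3.44 without supplemented cow 1. Superoxide dismutase (SOD) activity differed by 0.0200, -0.0912, 0.113 and 0.0977 on the same days, with 4 supplemented cows on day 4, and turned at the farthest to -0.0318 on day 0 without control cow 4, to 0.0885 on day 4 without control cow 1 and to -0.103 on day 14 without supplemented cow 2. In all, 0 of 20 determinations passed and 4 had an unadjusted exact p under 0.05. The smallest p that 6 against 6 cows can give is 0.00216.

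**Figure D4:**
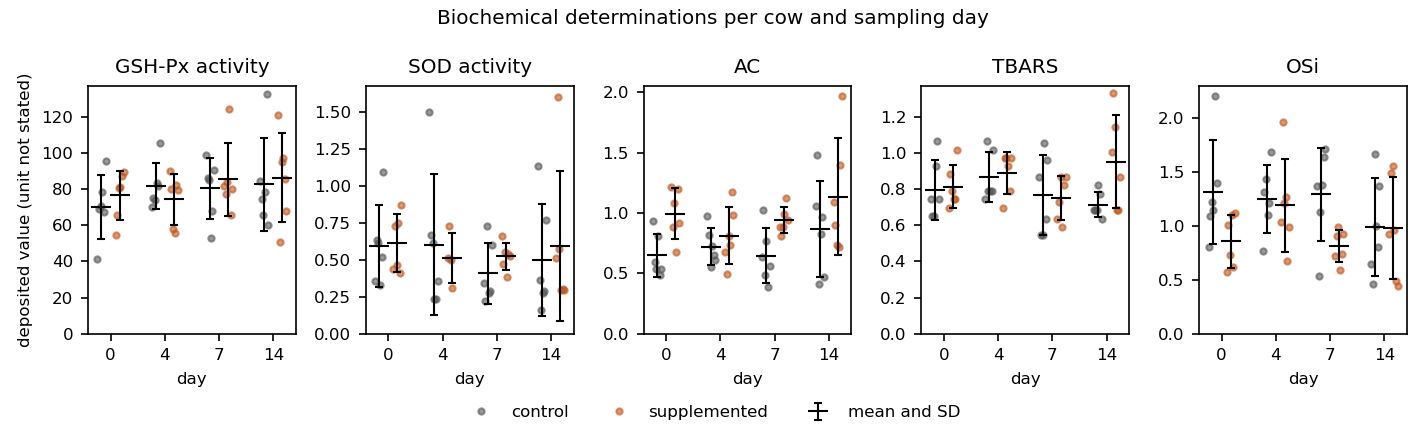
Deposited values of the 5 determinations in each cow (points, units not stated) on days 0, 4, 7 and 14, control in grey and supplemented in orange, with the mean and SD of each group. AC lies higher in supplemented cows on days 0 and 7 (0.938 against 0.644 on day 7) and OSi lower (0.810 against 1.29).

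Changes from the first sampling were compared as a test of group and time together. From day 0 to day 4 the mean difference in AC was -0.183 in supplemented and 0.0727 in control cows, which leaves -0.255 between the groups (exact p = 0.0563, adjusted p = 0.753). To day 7 the change in AC differed by -0.0523 between the groups (exact p = 0.669, adjusted p = 1), and that in TBARS to day 14 by 0.224 (exact p = 0.108, adjusted p = 0.753). The exact tests passed for 0 of 15 changes, and 0 had an unadjusted p under 0.05. Milk on day 30 was 37.7 ± 4.72 in supplemented and 35.2 ± 4.45 in control cows (SD, n = 6 each, unit not stated; difference 2.5, exact two-sided permutation p = 0.396), with a difference of 1.03 without supplemented cow 3 and 3.87 without control cow 6.

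The last comparison asked whether enzyme activity on day 7 went with the level of transcripts for enzymes of that kind across the 12 cows. The material of the activities is not stated in the sources used here, so these blood transcripts may not encode the enzyme that was measured. GSH-Px activity and GPX3 log2 CPM had Pearson's r of -0.370 (permutation p = 0.226, adjusted p = 0.572) and Spearman's rho of -0.678 (permutation p = 0.0182, adjusted p = 0.0909), with r of -0.382 without the 2 cows farthest from the median activity. For GPX1 r was -0.287 (permutation p = 0.343) and rho -0.420 (permutation p = 0.178), and for GPX4 r was -0.356 (permutation p = 0.251) and rho -0.559 (permutation p = 0.0634). SOD activity had r of -0.0297 (permutation p = 0.926) and rho of -0.0839 (permutation p = 0.800) with SOD1, and r of -0.123 (permutation p = 0.723) and rho of -0.322 (permutation p = 0.308) with SOD2. None of the 5 relations passed after adjustment. Without the 2 cows farthest from the median activity, r was -0.318 for GPX1, -0.373 for GPX4, 0.208 for SOD1 and -0.205 for SOD2. The cows left out were control cow 4 and supplemented cow 4 for GSH-Px, and control cows 2 and 3 for SOD. Supplemented cow 6, with the highest GPX3, therefore stayed in each relation.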

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

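All tests of explanations in this part were chosen after the results were seen. By Dixon's test, which compares the gap to the nearest value with the range, a cow or library stood apart in 21 of 149 groups of values examined. Of the 21, 10 belonged to supplemented cow 6. The 7.45 expected by chance holds only for independent, normally distributed values. The values examined included CPM near the floor and genes that rose together in the same cow, so 21 is not read as an excess over chance.

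In supplemented cow 6 genes of granulocytes stood far above the other cows: S100A12 was at 38950 CPM and HP at 2419. So did SOD2 at 4926 CPM and GPX3 at 68.8 CPM, which stand in no granulocyte list here. The immature granulocyte score was 7.37, against at most 2.68 in the other supplemented cows and at most 4.04, in control cow 4, in the control cows. The 10 most counted genes took 11.4% of the counts of supplemented cow 6 and mitochondrial genes 1.75%. With every library thinned to the smallest total, its neutrophil score was 9.65 against at most 7.16 in the other libraries, so the pattern remained at equal depth. The score is scaled to total counts and was 9.63 before, so thinning could move it little and is a weak test of depth. Of 13 neutrophil markers 12 were highest in this library, which restates the pattern, and they exceeded the median of the other libraries by 1.82 to 8.31 on the log2 scale rather than by a common amount, so a larger share of granulocytes and a different state of these cells cannot be told apart. The labels put this cow in no group apart from the other supplemented cows, so no explanation by group was tested.

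The pair of genes called by DESeq2 alone was far higher in supplemented cows 4, 5 and 6 than in the other cows. From the level in supplemented cow 6, 1150 counts of ENSBTAG00000053198 and 776 of ENSBTAG00000034185 would be expected in control cow 6, the next deepest library, which had 0 and 97, so depth does not account for them. Of 24 genes with a step of at least 3 on the log2 scale between on and off cows, 5 had all on or all off cows in 1 group (4 of them off in 2 cows), and 63.0% of the 924 splits of the cows gave as many. ENSBTAG00000053198 is among the 24 but ENSBTAG00000034185 is not, and any 3 cows fall in 1 group in 18.2% of draws, so a chance allocation stays open for the pair. In 23 of the 24 genes, which include granulocyte genes such as MMP9 and ALPL (named after their values were seen), on cows were found in both groups, but genotypes were not analysed here, so a donor variant and the supplement cannot be told apart for this pair.

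AC was higher and OSi lower in supplemented cows on days 0 and 7. The groups differed by 0.00411 ± 0.138 (SE) in the natural log of TBARS on day 7, -0.986% of the difference in that of OSi. AC gave 101% of it, as OSi equals TBARS divided by AC, so in these cows the lower OSi came from AC. Natural log TBARS less 50% of natural log OSi differed by 0.212 ± 0.105 (SE), so a TBARS share of 50% lay 2.02 SE away. With so few cows that distance does not exclude a share of 50% beyond these cows, so the source of the difference stays open there. Taking the 20 determinations together, 3.25% of the 924 splits of the cows gave at least 4 tests with an unadjusted exact p under 0.05. This count was chosen after the 4 were seen, and no determination passed on its own after adjustment. A chance allocation of the cows therefore stays open. The difference between groups in the change of AC from day 0 to day 7 was -0.0523, and since the day of supplementation is not given in the sources used here, a difference between the cows before supplementation cannot be told apart from an effect present by day 0.

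Other values far from the rest of their group were as follows. In supplemented cow 6, SLC30A1 was at 52.3 CPM, SLC39A8 at 10.6 CPM and SELENOW at 0.0828 CPM, a level of few counts. In control cow 5, TNF was at 265 CPM and IL1B at 1697 CPM, and GSH-Px activity on day 14 was 133. S100A12 was at 5476 CPM in control cow 4, and MT1A at 0.201 CPM in control cow 3, near the floor. In supplemented cow 5, TNF was at 37.0 CPM, ELF1 was low at 170 CPM, and haemoglobin genes took 0.037% of counts. GSH-Px activity on day 7 was 124 in supplemented cow 4, SOD activity on day 4 was 1.5 in control cow 1, and SOD activity on day 14 was 1.60 in supplemented cow 2.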

How the results depend on the processing

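Values under the authors' filter, the B cell minus T cell covariate, the first index covariate and without both libraries with the highest neutrophil scores come from tests chosen after the data were seen. Across 126 results, 1986 of 2183 values under another setting kept their direction and their side of the threshold, 170 turned their direction, 14 passed where the main value had not, 13 counts moved by over 1.5 times, and, with no edgeR or list call to lose, 0 lost one. Of the 126 results, 61 turned direction under at least 1 setting. List medians under fry and under the preset correlation are the main medians, so they could not turn. The count of differentially expressed genes was 0 in edgeR and limma under each alternative and without each library. It was 2 with DESeq2, on the same genes or with the authors' filter. Counts at an unadjusted p under 0.05, 191 in edgeR, ranged from 129 to 407 over other settings and from 121 to 390 without 1 library; the highest was with a surrogate variable. Of 462 splits of the 12 cows 100 were drawn, with up to 3497 genes and up to 1 list called; since every split reaches the real counts of 0, all 100 did, which tests nothing about chance. At an unadjusted p under 0.05, 79 of the 100 splits gave at least the real 191 genes (median of the others 392). The split with 3497 genes set control cows 1, 4 and 5 and supplemented cows 2, 4 and 6 against the rest, and 1 more called 2469, which points to a structure of the samples that crosses the groups. Both splits kept control cows 4 and 5 and supplemented cows 2 and 6 together. These cows scored 54.1, 63.6, 62.3 and 113 on the first principal component, against at most -8.20 in the others. They also had the lowest B cell marker scores (6.26, 5.95, 5.23 and 4.90). Their neutrophil (7.14, 5.94, 5.72 and 9.63) and monocyte (7.73, 7.45, 7.68 and 8.10) scores were the highest, so the structure is not one of B cells alone. The count of lists was 8 with a preset correlation and 0 under the other list settings and without each library. Of simulated 2-fold changes 15.5% were recovered in draws and 27% in thinned libraries, and of 4-fold changes 81.5% and 73.5%; the simulations did not vary depth, so the part that depth plays in this was not tested.

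Uncalled values turned direction as follows, and the cause was not tested. With base quality as a covariate, log2 fold changes were -0.28 for GPX1, -1.30 for GPX3, -0.038 for TXNRD1, -1.53 for SOD2, -0.10 for SLC39A8, -0.23 for NFE2L2, -0.21 for HMOX1, -0.014 for NFKB1, -0.91 for HP, 0.055 for EEF1A1 and -1.97 for S100A12. With a surrogate variable they were -0.093 for GPX1, -0.11 for GPX3, -0.021 for GPX4, -0.054 for SOD2 and -0.023 for HP. limma-voom gave 0.085 for SELENOP and 0.11 for IL1B, and with sample weights -0.035 for GPX1, 0.18 for SELENOP, 0.27 for TNF, 0.48 for IL1B and -0.011 for NFKB1. GPX4 was at -0.013 with upper-quartile scaling, -0.042 with no scaling factor and -0.031 with the first index as a covariate, and NFKB1 at -0.0081 with no scaling factor. Without supplemented cow 6 and control cow 4, values were -0.012 for GPX1, -0.25 for GPX3, -0.020 for TXNRD1, -0.060 for SOD2, -0.031 for NFKB1, and medians -0.12 for interferon-stimulated genes -0.11 for immature granulocyte, 0.22 for erythroid and 0.093 for plasma cell markers, -0.056 for NADPH oxidase and myeloid oxidants, -0.024 for the respiratory chain and 0.00049 for selenium incorporation. With the B cell minus T cell score as a covariate, GPX4 was at -0.0046 and list medians at -0.00084 for metallothioneins and zinc handling, -0.0015 for interferon-stimulated genes, -0.095 for complement and Fc receptors, 0.057 for selenium incorporation, and -0.080 for T cell, -0.17 for monocyte, 0.042 for erythroid, 0.032 for plasma cell and -0.0023 for NK and cytotoxic cell markers. With the neutrophil minus T cell score as a covariate, medians were 0.025 for erythroid and 0.024 for plasma cell markers and 0.043 for selenium incorporation, whose median was 0.0014 with filterByExpr and 0.017 with RLE scaling. Differences of medians were 1.52 for GSH-Px activity on day 4, -4.82 on day 7, 0.0187 for SOD activity on day 4, 0.0225 for TBARS on day 7 and 0.0414 for OSi on day 14, and natural log differences 0.0169 for SOD activity on day 4 and 0.00411 for TBARS on day 7. Medians over markers gave -0.0080 for gamma-delta T cells and -0.12 for plasma cells. The relation of SOD activity with SOD1 turned to r of 0.208 without the 2 cows farthest from the median activity.

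Without 1 library, log2 fold changes ranged from -0.087 to 0.36 for GPX1, -0.49 to 2.77 for GPX3, -0.054 to 0.081 for GPX4, -0.28 to 0.32 for SELENOP, -0.034 to 0.15 for SOD1, -0.36 to 3.04 for SOD2, -2.16 to 0.56 for TNF, -1.71 to 0.73 for IL1B, -0.00026 to 0.14 for NFKB1, 0.063 to 0.22 for CAT, 0.32 to 0.59 for MT2A, -0.31 to -0.031 for SLC30A1, 0.012 to 0.17 for COX1, -0.23 to -0.0078 for EEF1A1, -0.36 to 1.89 for HP and -0.97 to 3.63 for S100A12. The lowest values of GPX1, GPX3, SOD2, HP and S100A12 were without supplemented cow 6 and the highest of TNF and IL1B without control cow 5. List medians ranged from -0.43 to 3.73 for neutrophil granule genes, -0.14 to 2.83 for immature granulocyte markers, -0.45 to 2.57 for neutrophil markers, -0.19 to 0.65 for monocyte markers, -0.041 to 0.55 for T cell markers, -0.60 to 0.29 for TNF and NF-kB response, -0.13 to 0.89 for cytokines and receptors, -0.14 to 0.33 for interferon-stimulated genes, -0.090 to 0.71 for adhesion and migration -0.16 to 0.033 for ribosomal proteins, -0.18 to 0.037 for cell cycle, 0.033 to 0.19 for unfolded protein and heat shock response, -0.26 to 0.38 for complement and Fc receptors, -0.043 to 0.10 for copper handling, -0.0058 to 0.36 for iron and manganese handling, -0.050 to 0.12 for selenium incorporation, -0.016 to 0.80 for extracellular matrix, -0.044 to 0.023 for MHC class I presentation, -0.022 to 0.042 for the respiratory chain and -0.012 to 0.33 for NADPH oxidase and myeloid oxidants. Those of markers ranged from -0.16 to 1.04 for eosinophils, -0.21 to 0.42 for erythroid cells, -0.063 to 0.51 for gamma-delta T cells, 0.16 to 0.92 for NK and cytotoxic cells, -0.14 to 0.11 for plasma cells and -0.69 to 0.37 for platelets. Marker scores differed by -0.11 to 1.38 for neutrophils, 0.17 to 0.84 for eosinophils, 0.32 to 0.77 for basophils and mast cells, -0.036 to 0.47 for T cells, -0.22 to 0.29 for gamma-delta T cells, -0.029 to 0.64 for NK and cytotoxic cells, -0.034 to 0.17 for plasma cells, -0.50 to 0.16 for platelets and -0.21 to 0.35 for erythroid cells.

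Without 1 cow, 0 to 2 of the 20 determinations passed; both were reached without control cow 2, for AC on day 7 (0.243 to 0.371 over the omissions, adjusted p from 0.0216 to 0.314 over all alternatives) and OSi on day 7 (-0.633 to -0.397, adjusted p from 0.0216 to 0.346). Differences ranged from 0.395 to 11.2 for GSH-Px activity on day 0, -10.4 to -2.51 on day 4, -2.73 to 9.05 on day 7, -3.44 to 13.5 on day 14, -0.0318 to 0.120 for SOD activity on day 0, 0.0759 to 0.178 on day 7, -0.165 to 0.0885 on day 4, -0.103 to 0.225 on day 14, -0.0261 to 0.0690 for TBARS on day 0, -0.00153 to 0.0629 on day 4, -0.0603 to 0.0417 on day 7, 0.0192 to 0.154 for AC on day 4, 0.0987 to 0.389 on day 14, -0.554 to -0.273 for OSi on day 0, -0.215 to 0.0428 on day 4 and -0.129 to 0.122 on day 14. The milk difference ranged from 1.03 without supplemented cow 3 to 3.87 without control cow 6 (exact p from 0.158 to 0.706 over all alternatives).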

Other observations

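The test of CD5 in this part was chosen after the values were seen. The cows differed more in blood cell markers than the groups did. MS4A1, the B cell surface protein CD20, stood at 848, 1176, 855, 456, 376 and 1268 CPM in control cows 1 to 6 and at 1003, 161, 1320, 914, 1039 and 183 CPM in supplemented cows 1 to 6. CD3E, a subunit of the T cell receptor complex, was at 92.8, 124, 178, 371, 464 and 69.2 CPM in the control cows and at 107, 490, 68.1, 352, 164 and 315 CPM in the supplemented cows. In most libraries MS4A1 therefore exceeded CD3E, while in control cow 5 and supplemented cows 2 and 6 it did not. These genes and those named next were chosen after their values were seen.

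CD5, a receptor found on T cells and on a subset of B cells, varied less between cows than the other 17 T cell markers, with an SD of 0.43 on the log2 scale against 0.73 to 1.35. It was at 211, 305, 240, 202, 223 and 277 CPM in control cows and at 288, 316, 234, 210, 307 and 107 CPM in supplemented cows. A hypothesis is that part of its RNA may come from B cells. In a linear model of CD5 on CD3E and MS4A1 over the 12 cows, the partial correlation with MS4A1 was 0.461 (permutation p = 0.151), and 0.294 without the 2 cows farthest from the median MS4A1 (permutation p = 0.440), so the test did not separate a B cell source from a constant level in other cells. Of 16 other T cell markers, 1 had a partial correlation as high.

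RPL12, a ribosomal protein gene, had 6333, 3639 and 5705 counts in control cows 3, 4 and 5 and 4112 in supplemented cow 3, and at most 4 in each of the other 8 libraries. In the SOD sheet the value 0.613 stood for control cow 3 on days 0 and 4, 0.285 for control cow 5 on days 7 and 14, and 0.731 for control cow 3 on day 7 and supplemented cow 2 on day 0.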
